A study of Mus musculus with 9 samples.

How the data were processed

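Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in untreated naive CD4+ T cells of C57BL/6 mice. The 9 libraries came from 3 genotypes with 3 libraries each: WT, Stat6_KO (Stat6 knockout) and Il21e_KO. The labels name the last allele both Il21e KO and IL21KO and do not say which DNA it removes. They do not say either whether the replicates are separate animals, so the p-values measure the spread between these samples. According to the labels, naive cells were enriched with a commercial negative-selection kit, tagmented with the Nextera enzyme and sequenced with paired-end Illumina reads.

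The authors supplied 1 table of 115727 peaks on the mm9 mouse genome, shared by all 9 libraries. Their processing notes name Bowtie 1.3.0, MACS2 2.0 and HOMER without stating the role of each, or how peaks were merged or filtered. The deposited values are CPM, reads in a peak scaled to the reads in all listed peaks of the library: the columns share 1 total over the listed peaks, so the authors divided each library by its own reads in peaks. The headers of the gene columns were shifted against their contents and were read by content. Every value was a whole multiple of a step specific to its library, within 0.01 read for 100% of values. The step was taken as 1 read, which gave a whole count per peak. CPM alone cannot show whether the step is 1 read. The libraries held between 1049460 and 1802405 reads in peaks, and 1 read equalled between 0.555 and 0.953 CPM. A count of 0 allows up to 3 reads, which is between 1.66 and 2.86 CPM depending on the library. Intervals and these floors cover counting error only, since reads copied by PCR are not independent molecules.

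Peaks were kept for testing by the filterByExpr function of edgeR 4.0.16 on the recovered reads, with a minimum count of 10 and a minimum total of 15, which left 48287 peaks and set aside 67440. The test was limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), with all 9 libraries in 1 fit and 1 coefficient per genotype, and Benjamini-Hochberg adjustment over the peaks tested, at a false discovery rate (FDR) of 0.05. The design chosen before the data were examined named edgeR on counts, or limma-trend if the file held normalised values; since it held CPM, limma-trend was used, and edgeR on the recovered reads was added as an alternative. Log2 fold changes are given with the standard error (SE) of the fit. Group values are means ± SD of the CPM, n = 3 per group. A ratio of reads summed over a group's libraries, divided by the group's total reads, carries an exact 95% binomial (Clopper-Pearson) interval. Single library measures were compared by exact 2-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries.

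Gene assignments follow the table, which places each peak at a transcription start site (TSS), exon, intron, transcription termination site (TTS) or between genes. The 41627 intergenic peaks carry no gene in the table and were assigned here to the nearest TSS among the transcripts it lists. The peaks of Stat6, Il21 and its neighbour Il2, and those within 100 kb of these genes, were described first. Also fixed before the data were examined were 17 gene lists holding 233 genes, of which 204 had a tested peak, and the rule for naming genes. That rule takes the peaks past the threshold with separated groups and a mean of at least 1 CPM, and otherwise the 5 with the smallest p in each direction, leaving out pseudogenes and loci without a gene name. It adds, whatever their p, for a fixed set of genes the tested peak closest to the TSS. Of these Il4ra, Gata3, Bcl6, Cxcr5, Tcf7, Il7r, Cd44 and Tbx21 are given by a promoter peak and Foxp3 by a peak in exon 4, while Il4 had no tested peak. Genes outside the rule are named as such. With 5 calls both Agr2 peaks are given, although the rule takes 1 peak per gene. Lists were tested with camera at a preset correlation of 0.01 between peaks and repeated with an estimated correlation and with fry, with adjustment over the 51 tests of 17 lists in 3 comparisons.

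Both knockouts were compared with the same WT libraries. Their effects were therefore set beside 20 simulations with unchanged groups. The whole procedure was tested on simulated data with each fold change put into 66 or 67 peaks per comparison. It recovered between 83.3% and 87.9% of changes of 4-fold, between 28.4% and 35.8% of 2-fold changes and between 0% and 7.46% of 1.5-fold changes. False calls numbered 1 to 3 among 80 to 84. The adjusted threshold loosens as more peaks are called, and the real comparisons called 0 to 5. These shares are therefore likely too high for the real comparisons. The genome was scanned in 521 bins of 5 Mb for an excess of peaks at an unadjusted p under 0.01, with a 1-sided Fisher's exact test (hypergeometric) and Benjamini-Hochberg adjustment over the bins.

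Read counts of library pairs were compared by chi-square per degree of freedom to look for a library entered more than once. It was under 1, which is less spread than independent counting of reads gives, in 5 of 9 pairs within a genotype and in 19 of 27 pairs across genotypes. Since this held across genotypes as well, all 9 libraries were kept as separate. The intervals and floors treat the counts as independent reads, which this spread does not bear out, so they are approximate. The replicate numbers did not pair the libraries: 4 of 9 libraries matched best with their own number in another genotype, and 2 of 9 same-number pairs correlated above 0.1. Alternatives covered the normalisation (DESeq2 1.42.0 size factors, TMM, cyclic loess), the low-value filter, the pseudocount, the tool (edgeR, DESeq2, limma-voom, array weights), the libraries in the fit, the replicate number as a block and each library left out in turn. The planned change from TMM to library totals is the scaling of the deposited values themselves and needed no run.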

Results

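Open chromatin was profiled in naive CD4+ T cells, the resting helper T cells that have not yet met antigen, from WT, Stat6_KO and Il21e_KO mice, with 3 libraries per genotype. STAT6 is the transcription factor that carries the interleukin-4 signal and directs helper cells toward the Th2 fate. IL-21 is a cytokine of activated and follicular helper T cells. The WT libraries held 1634247, 1284426 and 1550677 reads in peaks, the Il21e_KO libraries 1049460, 1586954 and 1802405, and the Stat6_KO libraries 1759775, 1698387 and 1634889.

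Among the 9 libraries, Il21e_KO 1 stood apart. It had no read in 27200 of the 115727 peaks (23.5%), against 3898 to 12916 peaks in the others. TSS peaks held 42.7% of its reads, against 31.6% to 36.4%, and its mean correlation with the other libraries was 0.839, against at least 0.876. Its column header carries the number 1 where the others carry 7 to 9 and 11 to 15. The first principal component, with 47.8% of the variance, was carried by this library. By exact 2-sided permutation tests (n = 3 per group), reads in peaks gave p = 0.1 for Stat6_KO against WT and p = 1 for Il21e_KO against WT, and the TSS share gave p = 0.3 and p = 0.8, where 0.1 is the smallest p possible. Peaks without a read numbered 4950 ± 1029 in Stat6_KO, 10543 ± 3320 in WT and 12504 ± 12752 in Il21e_KO (SD, n = 3; exact permutation p = 0.1 for Stat6_KO and p = 1 for Il21e_KO against WT), so the Stat6_KO libraries covered more peaks than WT.

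**Figure D1:**
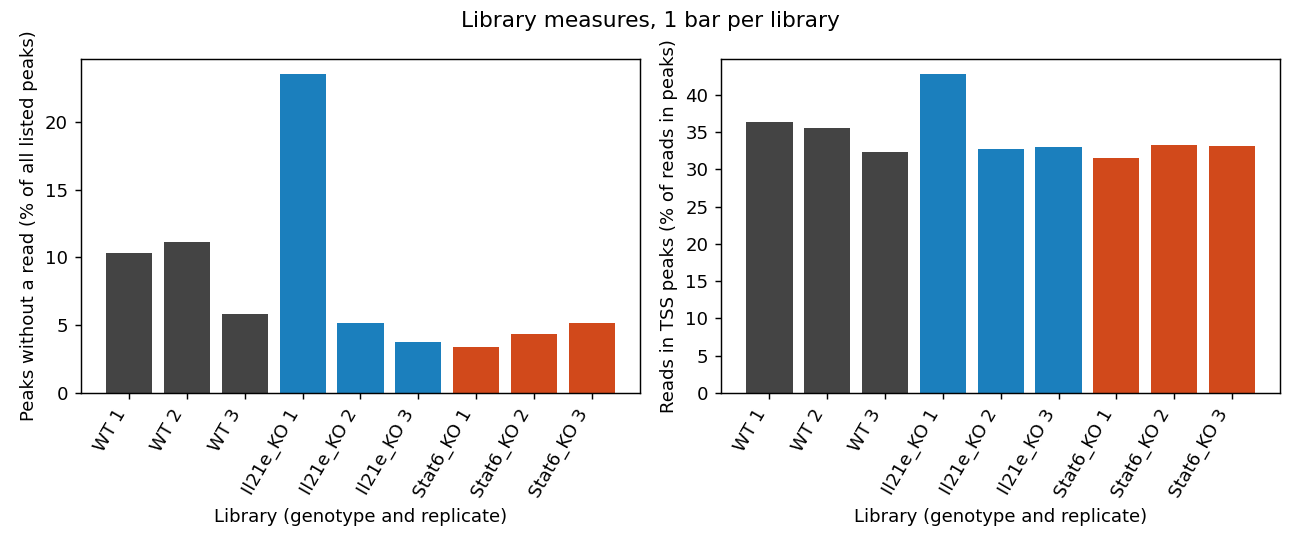
Share of the listed peaks without a read (left, %) and share of reads in TSS peaks (right, % of reads in peaks), 1 bar per library, coloured by genotype. Il21e_KO 1 is the highest in both, at 23.5% and 42.7%.

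The first question was whether the edited loci carry a trace of the knockout. At Stat6, on chromosome 10, the promoter peak (127078755 to 127081311) stayed open in Stat6_KO cells, at 65.2 ± 2.89 CPM against 70.7 ± 13.6 in WT (SD, n = 3). Inside the gene, an exon 12 peak (127091973 to 127092691) held 5, 3 and 3 reads in the Stat6_KO libraries against 11, 9 and 19 in WT, a log2 fold change of -1.59 ± 0.39 (SE). Adjusted over the 14 locus peaks alone it passed (limma-trend adjusted p = 0.00976). It passed in the same way against Il21e_KO (-1.35 ± 0.39, limma-trend adjusted p = 0.0193). An exon 16 peak (127094700 to 127095673) was higher in Stat6_KO, at 19.3 ± 4.00 CPM against 8.60 ± 2.80 in WT and 5.53 ± 3.17 in Il21e_KO. Its difference passed over the locus alone against Il21e_KO (1.77 ± 0.36, adjusted p = 0.00191) and missed against WT (1.11 ± 0.36, adjusted p = 0.0502). Over all peaks tested, 0 of the 14 Stat6 locus peaks passed in either limma-trend comparison with all 9 libraries.

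The exon 12 call rests on few reads, and without WT 3 it missed the threshold over the locus alone (-1.34, adjusted p = 0.0729, the highest over its alternatives, which went down to 0.000167). Against Il21e_KO it missed in a fit of the 2 groups alone (adjusted p = 0.121, with a range of 0.000280 to 0.121 over the alternatives) and without Il21e_KO 2, Il21e_KO 3, Stat6_KO 2 or Stat6_KO 3. At Il21, on chromosome 3, the 6 peaks assigned to the gene held at most 5 reads in any library, below the filter, and 0 of the 21 tested peaks within 100 kb passed over the locus alone in Il21e_KO against WT (lowest adjusted p = 0.567, limma-trend; lowest unadjusted p = 0.0270). The promoter peak of Il2 (37024505 to 37025635), the neighbouring growth factor gene of T cells, stood at 18.5 ± 3.97 CPM in Il21e_KO and 19.5 ± 2.80 in WT. Among the 16 peaks near Il21 with a WT mean of 10 or more reads, 0 were at or under 3 reads in every Il21e_KO library, so the removed DNA was not visible in the listed peaks at this depth.

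**Figure D2:**
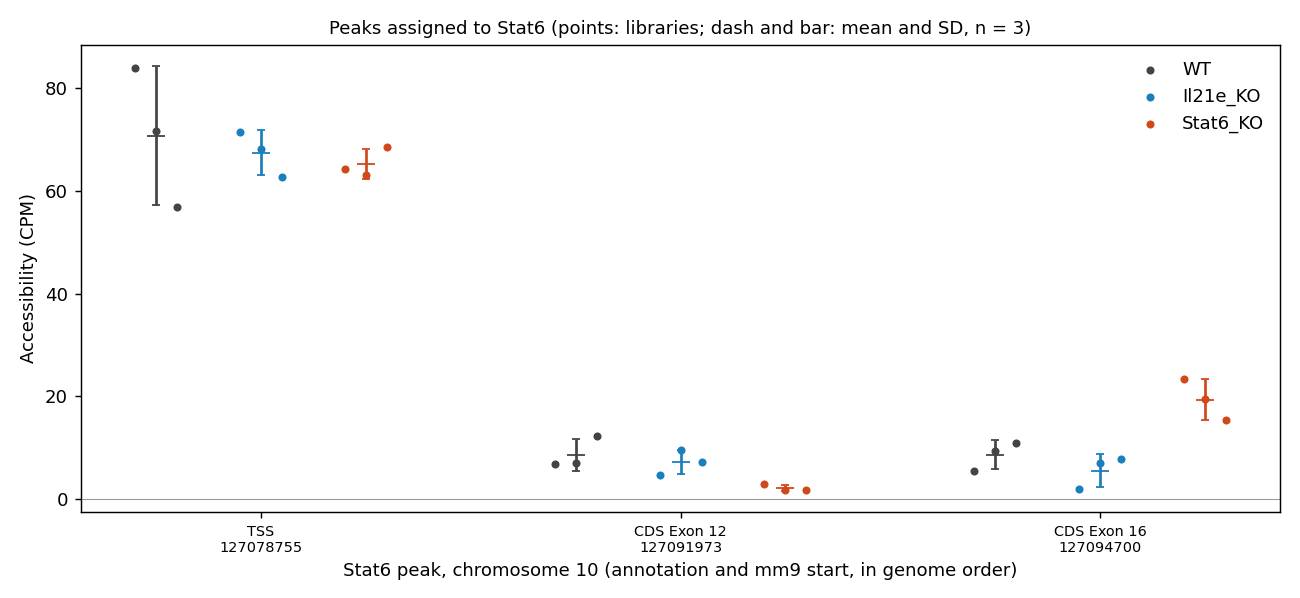
Accessibility (CPM, linear axis) at the 3 peaks assigned to Stat6, in genome order; points are libraries, the dash and bar are mean and SD, n = 3. The exon 12 peak is lowest and the exon 16 peak highest in Stat6_KO, with 19.3 CPM on average at exon 16.

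The comparison of Stat6_KO with WT asks how naive CD4+ T cells change their open chromatin without STAT6. Accessibility fell at 5 intergenic peaks, on chromosomes 11 and 12, and rose at 0. The deepest loss lay 10.1 kb from Scpep1os, a transcript from the strand opposite Scpep1 (chromosome 11, 88756609 to 88757743), where Stat6_KO kept 0.393 ± 0.680 CPM of the 31.2 ± 8.10 in WT (SD, n = 3). A peak 217 kb from Il12b, which encodes the shared subunit of interleukins 12 and 23 (chromosome 11, 43996386 to 43997422), went from 25.1 ± 3.85 to 1.20 ± 1.04 CPM. On chromosome 12 the losses lay 56.7 kb from Snx13, a sorting nexin of endosomal traffic (35674659 to 35675659, 29.9 ± 1.75 to 3.09 ± 2.24 CPM), and 96.1 kb and 76.9 kb from Agr2, a disulfide isomerase of secretory cells (36622808 to 36624051 and 36642250 to 36642901).

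The log2 fold changes were -4.60 ± 0.31 (SE) for the Scpep1os peak (FDR 1.31e-06), -3.71 ± 0.34 for Il12b (FDR 6.41e-05), -3.05 ± 0.28 for Snx13 (FDR 6.41e-05), and -3.24 ± 0.37 (FDR 0.00126) and -2.92 ± 0.43 (FDR 0.0259) for Agr2. In each, all 3 Stat6_KO libraries lay below all 3 WT libraries. Summed over libraries, the Scpep1os peak had 137 reads in WT and 2 in Stat6_KO, a ratio per total read of 78.1 (95% interval 21.2 to 651). The Il12b peak had 111 and 6 (ratio 21.1, 9.38 to 58.7), the Snx13 peak 134 and 16 (9.54, 5.67 to 17.2), and the Agr2 peaks 53 and 2 (30.2, 7.96 to 256) and 43 and 2 (24.5, 6.38 to 209). The Il12b call was lost with limma-voom, the weaker Agr2 call with DESeq2, limma-voom, a pseudocount of 0.25, the replicate number as a block or without any 1 of the WT libraries, Il21e_KO 2, Il21e_KO 3 or Stat6_KO 2, and the other Agr2 call without WT 2 or WT 3.

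**Figure D3:**
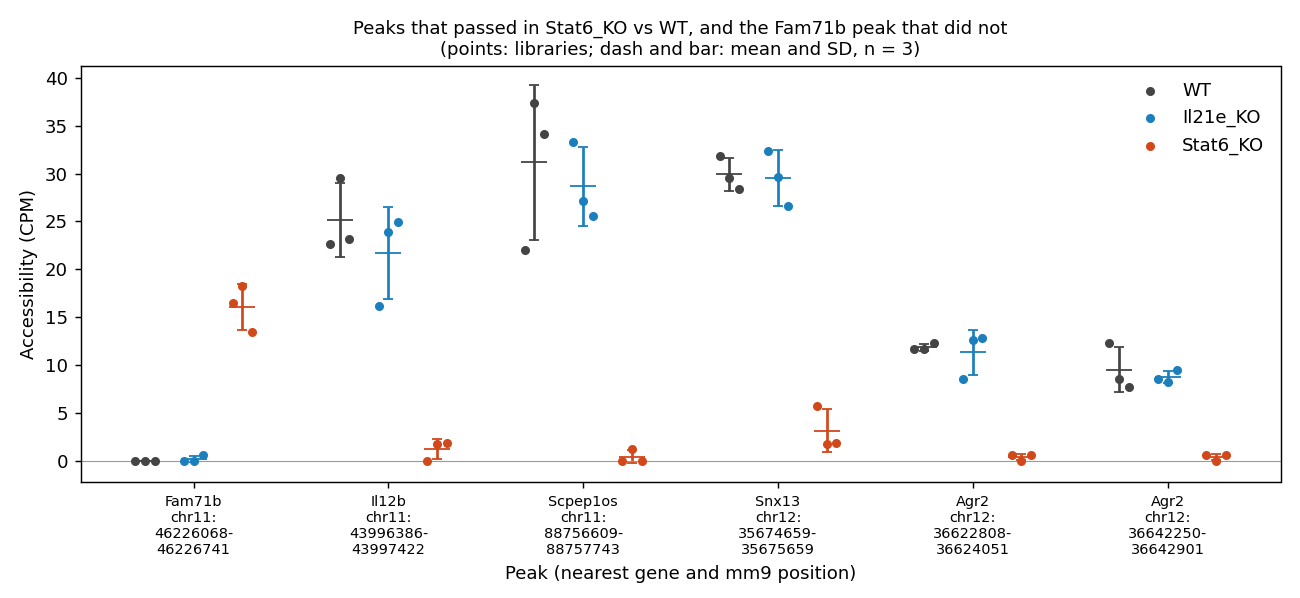
Accessibility (CPM, linear axis) at the 5 peaks that passed in Stat6_KO against WT and at the Fam71b peak that did not pass by limma-trend; points are libraries, the dash and bar are mean and SD, n = 3. Stat6_KO lies near 0 at the called peaks, such as 0.393 CPM near Scpep1os, and is the genotype with signal at the Fam71b peak.

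With 0 peaks passing upward by limma-trend, 1591 peaks reached an unadjusted p under 0.05 in either direction. EdgeR called 6 peaks, DESeq2 6 and limma-voom 4, with 1 higher in each, a peak near Fam71b. The smallest upward p belonged to an intergenic peak on chromosome 12 (94468597 to 94469311), 1381 kb from the nearest TSS, of the ER degradation gene Sel1l (1.06 ± 0.21, FDR 0.607). It was followed by the Fam71b peak, 8.17 kb from the gene (chromosome 11, 46226068 to 46226741), with 0 reads in every WT library and 29, 31 and 22 in Stat6_KO, at least 7.89-fold higher against a floor of 3 reads per library (FDR 0.939, limma-trend). That peak passed with edgeR (adjusted p = 5.28e-05), DESeq2 and limma-voom, without a filter, with cyclic loess, a pseudocount of 5 or array weights, in a fit of the 2 groups and without Il21e_KO 1, alone or with WT 1, with adjusted p from 7.24e-07 to 1.00 over the alternatives. Next came intron 2 of the MAP kinase phosphatase gene Dusp10 (1.31 ± 0.28), the TTS of the tetraspanin gene Cd53 (1.44 ± 0.31) and the TTS of the lysophospholipid receptor gene P2ry10 (1.21 ± 0.27); none of these passed by limma-trend. Groups did not overlap at 13.2% of peaks, where chance gives 10%.

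Although it takes no part in the contrast, Il21e_KO 1 moved the number of calls through the shared fit: without it, 61 peaks passed in Stat6_KO against WT, 28 higher and 33 lower, and the 5 named above were among them. Without WT 1 there were 9 calls, and 3 without WT 2 or without WT 3. The median SE was 0.242 with it and 0.200 without. The following genes of that wider set were chosen after their values were seen. The promoter of Ahr, a ligand-activated transcription factor of helper T cells (chromosome 12, 36218657 to 36220089), was lower by this fit (-0.88), as was intron 1 of Il7r, the receptor for the survival cytokine IL-7 (-0.94). The Stat6 exon 16 peak (1.11) was higher, as were the Dusp10, Cd53 and P2ry10 peaks. The Stat6 exon 12 peak was lower and passed over all peaks in this fit (-1.59, FDR 0.0274). Of the 61, 10 lay at a TSS and 16 in the 5 Mb regions described next, among them the Ahr, Fam71b, Snx13 and Agr2 peaks. Those regions were picked for low p in the same comparison, so the overlap lends them no further weight.

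Differing peaks gathered in a few regions of the genome. In Stat6_KO against WT, 4 of 521 bins of 5 Mb held more peaks at an unadjusted p under 0.01 than their share. They were chromosome X from 165 to 170 Mb (6 of 27 peaks, FDR 3.61e-06), chromosome 11 from 45 to 50 Mb, which holds Fam71b (9 of 149, FDR 4.10e-05), chromosome 12 from 35 to 40 Mb, which holds Snx13, Agr2 and Ahr (5 of 40, FDR 0.000468), and chromosome 14 from 50 to 55 Mb (8 of 164, FDR 0.000503). Within 10 Mb of Stat6 itself there were 0 called peaks and 8 of 437 at an unadjusted p under 0.01, against 257 of 47850 elsewhere (odds ratio 3.45, Fisher's exact p = 0.00306, 2-sided). All 5 called peaks were intergenic, a class holding 33.5% of tested peaks (Fisher's exact p = 0.00425). Among the 265 peaks at an unadjusted p under 0.01, 14.3% lay at a TSS, against 24.7% of tested peaks (Fisher's exact p = 5.63e-05). This was not particular to Stat6_KO: in Il21e_KO against WT the share was 14.2% of 211 (Fisher's exact p = 0.000289), and in Stat6_KO against Il21e_KO 26.6% of 365 (Fisher's exact p = 0.394).

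On chromosome 14 the signal came from an interval of 17 intergenic peaks (53661607 to 53755104) that lies between the annotated genes Olfr1509 and Dad1, where the variable segments of the T cell receptor alpha chain are encoded. The Stat6_KO libraries held 3, 3 and 1 reads over the interval and WT 1 held 5, whereas WT 2 and WT 3 held 250 and 234 and the Il21e_KO libraries 138, 290 and 320.

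**Figure D4:**
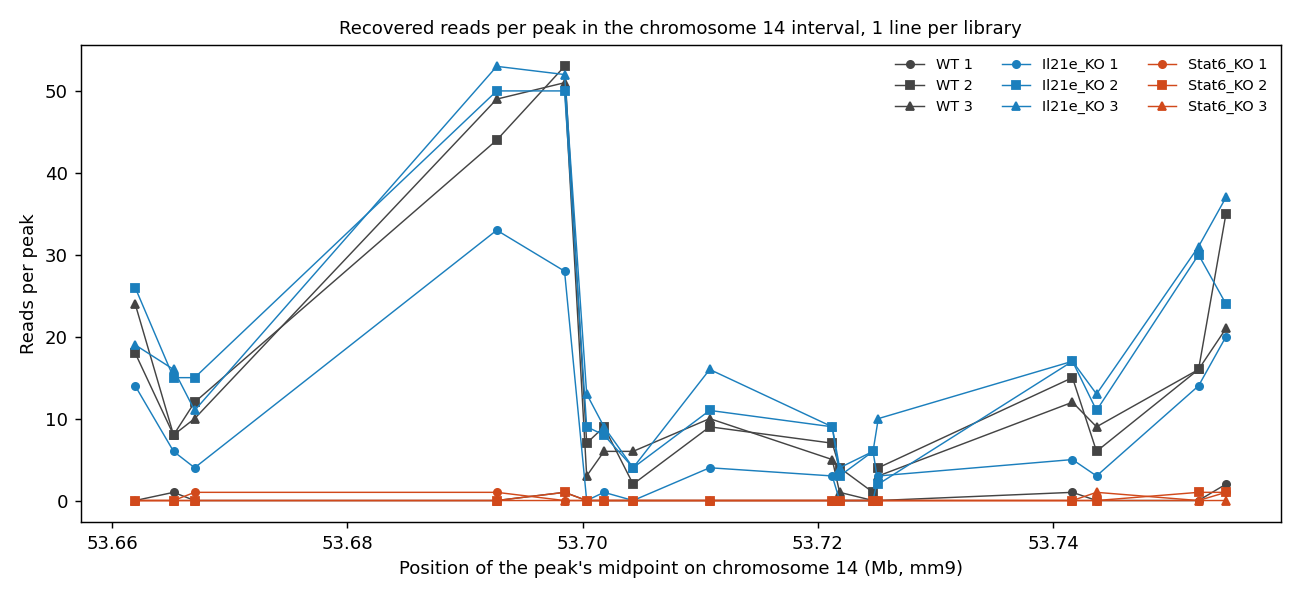
Recovered reads per peak (linear axis) along the chromosome 14 interval (peak midpoint, Mb, mm9), 1 line per library. WT 1 and the 3 Stat6_KO libraries lie near 0 throughout, with 5, 3, 3 and 1 reads over the interval.

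The helper T cell programmes showed no shift past the threshold in Stat6_KO. Of the 17 gene lists, 0 passed camera against WT (lowest FDR 0.495), 0 at an unadjusted p under 0.05, and 0 passed fry (lowest FDR 0.796). The 72 peaks of the IL-4 and STAT6 response list had a median log2 fold change of -0.03, the 63 Th2 peaks -0.02 and the 436 peaks of the naive and quiescent list -0.03, and 0 of their members passed. The other T cell lists had medians of -0.01 (early T cell receptor response), -0.06 (Th1), -0.01 (follicular helper), -0.01 (Th17), 0.00 (regulatory), -0.03 (cytokine and JAK-STAT), -0.10 (interferon response) and -0.09 (memory and effector), and ubiquitous genes -0.01. In the Th17 list the Ahr promoter passed when adjusted over the list alone (-0.88 ± 0.17, adjusted p = 0.00313), and missed over all peaks (FDR 0.607); it lies in the chromosome 12 region. Promoters of the Th2 regulator Gata3 (-0.14 ± 0.21), the IL-4 receptor gene Il4ra (-0.10 ± 0.22), the follicular regulator Bcl6 (-0.34 ± 0.19) and its partner receptor Cxcr5 (-0.58 ± 0.20) did not pass. Neither did those of the naive-cell genes Tcf7 (-0.23 ± 0.14) and Il7r (-0.18 ± 0.25), the memory marker Cd44 (0.25 ± 0.18), the Th1 regulator Tbx21 (-0.32 ± 0.20), or an exon 4 peak of the regulatory T cell factor Foxp3 (-0.38 ± 0.27), each at FDR 1.00. Il4 had no tested peak. Markers of other cell types had medians of 0.06 (B cells), -0.07 (CD8 T cells), -0.02 (erythroid), -0.03 (myeloid) and -0.06 (NK cells), and 0 passed.

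The comparison of Il21e_KO with WT asks what the Il21e allele changes in naive cells. No peak passed by limma-trend (lowest FDR 0.875), while 1698 reached an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom each called 0. The smallest p belonged to an intergenic peak 56.9 kb from Pkdcc, a secreted tyrosine kinase gene (chromosome 17, 83557263 to 83558202), with 1, 3 and 4 reads in Il21e_KO and 13, 25 and 28 in WT (-2.53 ± 0.43, FDR 0.875). The Stat6_KO libraries held 7, 5 and 5 reads there. Other low values lay at intron 3 of the glycosylation gene Ispd (-1.80 ± 0.36), the TSS of Asb16 (-1.19 ± 0.27), exon 2 of Cmtm7 (-1.25 ± 0.30) and near the imprinted transcript Hymai (-1.09 ± 0.27). High values lay at the Sel1l peak (0.95 ± 0.21), intron 5 of Osbpl9 (0.97 ± 0.23), the TSS of Zfp882 (0.79 ± 0.21) and near Smad2, a TGF-beta signalling gene (0.91 ± 0.24), and Irs2, an insulin receptor substrate (1.06 ± 0.29). Groups did not overlap at 7.28% of peaks, where chance gives 10%.

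Without Il21e_KO 1, 2 peaks passed: the Pkdcc peak (-2.31) and the TSS of 1700030C10Rik (1.21), which was chosen after its values were seen. Neither stood apart in Il21e_KO alone. By the same fit the Pkdcc peak was also lower in Stat6_KO against WT (-1.82, FDR 0.00619). The 1700030C10Rik peak held 16, 19 and 20 reads in WT and 42, 41 and 21 in Stat6_KO. Il21e_KO 2 and 3 held 50 and 51 there, but the left-out Il21e_KO 1, the shallowest library, held 8. With all libraries the Pkdcc peak also passed in Il21e_KO against WT without a filter (FDR 0.0333) and with array weights (FDR 0.0193), with adjusted p from 0.00182 to 1.00 over the alternatives. Changes under 2-fold would mostly be missed at this depth and spread, since 28.4% of simulated 2-fold changes were recovered. That share is likely too high here, because the simulated data held many more calls. Larger changes could be missed too, as the Pkdcc peak at -2.53 had FDR 0.875 in the fit as reported.

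Among the gene lists, 0 passed camera in Il21e_KO (lowest FDR 0.159), with 1 at an unadjusted p under 0.05, and 0 passed fry. That list was Th17, whose 34 peaks had a median log2 fold change of -0.19 (unadjusted p = 0.00312, adjusted p = 0.159, with a range of 0.0933 to 0.996 over the alternatives). Without Il21e_KO 1 the adjusted p was 0.658 and with an estimated correlation 0.892, and with 1 peak per gene the direction was up (adjusted p = 0.951). Its members with the lowest p were an intron 1 peak of Rora (-0.78 ± 0.27), a nuclear receptor of Th17 cells, and an intergenic peak of Ahr (-0.89 ± 0.38), neither of which passed, over all peaks or adjusted over the list alone. Follicular helper peaks, 173 in number, had a median of -0.08 and the Cxcr5 promoter stood at -0.52 ± 0.20, while the Bcl6 promoter stood at -0.15 ± 0.19. Medians in the other T cell lists were -0.07 (Th2), -0.03 (IL-4 and STAT6 response), -0.08 (Th1), -0.04 (regulatory), 0.02 (early T cell receptor response), -0.03 (cytokine and JAK-STAT), -0.04 (interferon response), -0.11 (memory and effector), -0.02 (naive and quiescent) and -0.01 (ubiquitous). Of markers of other cell types, medians were -0.11 (B cells), -0.13 (CD8 T cells), 0.03 (erythroid), -0.07 (myeloid) and -0.05 (NK cells). The exon 4 peak of Foxp3 (-0.39) did not pass, nor did the promoters of Tcf7 (-0.30), Tbx21 (-0.32), Cd44 (0.27), Il7r (-0.20), Il4ra (0.14) or Gata3 (-0.03).

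The direct comparison of Stat6_KO with Il21e_KO tests whether the knockouts differ from each other; WT libraries enter only through the spread estimated over all 9 libraries. The same 5 peaks near Scpep1os, Il12b, Snx13 and Agr2 fell in Stat6_KO and 0 rose by limma-trend, with log2 fold changes of -4.51 ± 0.31 (FDR 1.83e-06), -3.49 ± 0.34 (FDR 0.000159), -3.02 ± 0.28 (FDR 9.90e-05), and -3.16 ± 0.37 (FDR 0.0018) and -2.83 ± 0.43 (FDR 0.0385) for Agr2. Il21e_KO stood close to WT at these peaks, for example 28.7 ± 4.14 CPM near Scpep1os and 21.7 ± 4.79 near Il12b. Among peaks that did not pass, the smallest upward p lay at Ispd intron 3 (1.82 ± 0.36, FDR 0.406), the Stat6 exon 16 peak (1.77 ± 0.36, FDR 0.506), Fam71b (82 reads summed in Stat6_KO and 1 in Il21e_KO, ratio 71.5, 95% interval 12.5 to 2857), the Mediator gene Med7 (1.03 ± 0.24) and Mtx2, a mitochondrial import gene (0.99 ± 0.23). In all, 2744 peaks reached an unadjusted p under 0.05, and edgeR called 10 (2 higher), DESeq2 7 (1 higher) and limma-voom 4 (1 higher). The Fam71b peak, which missed by limma-trend (FDR 0.780), passed with these 3 tools, without a filter, with a pseudocount of 5 or array weights, and without Il21e_KO 1, alone or with WT 1 (adjusted p from 2.81e-05 to 0.988 over the alternatives). Without Il21e_KO 1, 17 peaks passed, 4 higher and 13 lower, including the same 5, and without WT 1 there were 9. The Il12b call was lost with limma-voom. The weaker Agr2 call was lost with DESeq2, limma-voom, a pseudocount of 0.25, the replicate number as a block or without any 1 of the WT libraries, Il21e_KO 2 or 3, or any 1 of the Stat6_KO libraries, and both Agr2 calls in a fit of the 2 groups alone.

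The regional scan gave 3 bins here, on chromosome 12 from 35 to 40 Mb (7 of 40 peaks), chromosome 14 from 50 to 55 Mb (10 of 164) and chromosome 11 from 45 to 50 Mb (8 of 149), which were among the 4 found against WT. In Il21e_KO against WT it gave 0 bins. Of the 17 lists, 0 passed camera (lowest FDR 0.495), with 1 at an unadjusted p under 0.05, the early T cell receptor response list (196 peaks, median -0.05, unadjusted p = 0.0401). Its adjusted p was 0.892 with an estimated correlation and 0.979 without Il21e_KO 1. When each gene was represented by its peak closest to the TSS, that list passed (FDR 0.00149, range 0.00149 to 0.979 over the alternatives), and so did the cytokine and JAK-STAT list (FDR 0.0283, range 0.0283 to 0.996). Neither call held with an estimated correlation (adjusted p = 0.874 for both) or without Il21e_KO 1 (FDR 0.448 and 0.995), the library with 42.7% of its reads at TSS peaks. Adjusted over the list alone, Ahr (-0.73 ± 0.17, adjusted p = 0.0189) and Rora intron 1 (0.99 ± 0.27, adjusted p = 0.0308) passed in the Th17 list, and the Stat6 exon 16 peak in the cytokine list (adjusted p = 0.0321).

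The remaining list medians in Stat6_KO against Il21e_KO were 0.23 (Th17), 0.08 (follicular helper), 0.08 (Th2), 0.05 (IL-4 and STAT6 response), 0.04 (Th1), 0.05 (regulatory), 0.01 (cytokine and JAK-STAT), -0.05 (interferon response), 0.06 (memory and effector), -0.01 (naive and quiescent) and -0.01 (ubiquitous). For markers of other cell types they were 0.18 (B cells), -0.01 (CD8 T cells), -0.01 (erythroid), 0.08 (myeloid) and -0.05 (NK cells). None of these promoters nor the Foxp3 peak passed, the largest difference among them being at Il4ra (-0.24 ± 0.22). The sign differed among median, mean and camera in 12 of the 51 tests: for the regulatory list in Stat6_KO against WT; for the cytokine, interferon, naive, erythroid, NK and ubiquitous lists in Il21e_KO against WT; and for the cytokine, interferon, naive, CD8 and erythroid lists in the direct comparison.

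The effects of the knockouts were also compared across all 48287 tested peaks, which are not independent replicates. Their correlation was 0.313, against 0.422 in simulations where neither knockout changed anything and both shared the WT libraries. The covariance was 0.0244, against 0.0323 in the simulations, a difference of -0.00787. At an unadjusted p under 0.05, 128 peaks were higher in both knockouts and 83 lower in both; independent lists would share 8.93 and 18.9, and the simulations with shared WT libraries gave 304 and 333. Without Il21e_KO 1 the order was reversed: against simulations of the same 8 libraries, the correlation was 0.580 against 0.551, the covariance 0.0434 against 0.0323, and the shared peaks 625 higher and 596 lower against 470 and 512. Whether the knockouts agree beyond the shared controls thus rests on that library. With all 9 libraries, unchanged groups sharing the WT libraries gave more shared peaks than observed. The observed lists held 809 (Stat6_KO) and 533 (Il21e_KO) peaks higher, and 782 and 1165 lower. The sizes of the simulated lists were not set beside these, so fewer shared peaks may only reflect shorter lists. An excess over independent lists can still arise without a common effect of the knockouts. The 3 WT libraries are too few to be split between the knockouts.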

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

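Chosen only after the result was seen were the tests of a genome-wide effect, of linked DNA on other chromosomes, of Stat6 loss in WT 1, of the Il21e allele, of other splits and of strain variants without the chromosome 14 bin; the rest were set before their values were known.

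At 5 peaks the effects of the knockouts against WT differed from each other, by the direct test of Stat6_KO against Il21e_KO. The difference was -4.51 on the log2 scale near Scpep1os, -3.49 near Il12b, -3.02 near Snx13 and -3.16 and -2.83 at the Agr2 peaks. All 3 Stat6_KO libraries lay below all 6 others at each of them. The 6 libraries of Stat6_KO and WT form 10 splits into 3 and 3, too few for a share under 0.05: 1 of the 10 splits called as many peaks as the real one, which called 5, and the highest of the other splits called 0. For Stat6_KO and Il21e_KO the numbers were again 1 of 10 splits, with 5 calls in the real one and 0 in the highest of the others. For Il21e_KO and WT all 10 of 10 splits called as many as the real one, since the real one and the highest of the others both called 0.

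The first pattern is the gathering of peaks at an unadjusted p under 0.01 in 4 bins of 5 Mb on chromosomes 11, 12, 14 and X in Stat6_KO against WT. Other splits of the 6 libraries gave at most 1 such bin against the real 4, which restates the pattern and leaves open an effect of Stat6 loss spread over the genome; linkage to the Stat6 allele cannot reach these bins, since 0 of the 4 lie on chromosome 10. DNA of another strain carried along around Stat6 itself could account for the region near the gene. Differing peaks were more frequent there even without the peaks of Stat6 (6 of 434, odds ratio 2.60, Fisher's exact p = 0.0324). With those peaks, Il21e_KO against WT, without that allele, gave 4 of 437 (odds ratio 2.13, Fisher's exact p = 0.126). Stat6_KO against Il21e_KO gave 11 of 437 (odds ratio 3.46, Fisher's exact p = 0.000560). Within 5 Mb, Stat6_KO against WT gave 7 of 214 (odds ratio 6.27) and Il21e_KO against WT 2 of 214 (odds ratio 2.16, Fisher's exact p = 0.240). Whether the excess is particular to Stat6_KO stays open, since the Il21e_KO values rest on few peaks. Strain variants away from Stat6 may account for some of the other regions. Of the 28 differing peaks in the 4 bins, 13 (46.4%) were at or under 3 reads in every library of 1 group. Elsewhere 5 of 237 (2.11%) were (Fisher's exact p = 6.37e-11). Without the chromosome 14 bin, which held 7 of the 13, it was 6 of 20 (30.0%, Fisher's exact p = 3.71e-05). By bin, such peaks were 3 of 9 on chromosome 11, 2 of 5 on chromosome 12 and 1 of 6 on chromosome X. The count therefore says little about the region on X. Neighbouring peaks are not independent, so these p are too small, and a direct effect of STAT6 at single peaks such as those near Scpep1os and Il12b stays open, since any such variants confined to Stat6_KO would go together with Stat6 loss.

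The second pattern is the interval on chromosome 14, near the T cell receptor alpha variable segments, with almost no reads in WT 1 and all Stat6_KO libraries. Stat6 loss cannot be what removed them in WT 1, which held 3 reads over the 5 peaks that follow this division, where WT 2 and WT 3 held 166 and 161. A mislabelled Stat6_KO library is argued against by the 5 peaks called in Stat6_KO against Il21e_KO, where WT 1 held 164 reads, within the 104 to 179 of Il21e_KO and above the 8 to 12 of Stat6_KO. WT 1 entered the choice of these peaks through the shared spread, which favours peaks where it resembles the other WT libraries. With WT 1 left out of the fit, 4 of the 5 still passed, among 9 calls. Mice of different colonies or substrains remain possible: outside the interval 0 peaks followed the same division of the 9 libraries, against at most 1 for any other of the 126 divisions, but a single variant would leave no other peak, so this cannot be told apart from a variant carried by some mice.

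The third pattern is Il21e_KO 1. Lower depth alone falls short, since the other libraries thinned to its 1049460 reads had at most 19833 peaks without a read, against its 27200. The Il21e allele is argued against by the other Il21e_KO libraries, with at most 5952 such peaks, fewer than the 12916 of the highest library of the other genotypes. Cells of another type would add peaks of their own. In this library 0 peaks with 10 or more reads were at 3 or fewer in the 8 others, against at most 4 for another library. The counts were not matched for depth, and 1 read is 0.953 CPM here but 0.555 CPM in the deepest library. A count of 0 is therefore easily reached and speaks at most against a large share of cells with peaks of their own. A library prepared or sequenced apart from the rest, as its header number might suggest, was not tested, since there is only 1 such library.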

How the results depend on the processing

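Array weights, edgeR on recovered reads, scaling by TMM, the fit without WT 1 and Il21e_KO 1, the unadjusted p of 0.01 with its windows, fry, the assignment by the authors alone, 1 peak per gene with an estimated correlation, without Il21e_KO 1 or both, and the simulations of 8 libraries were chosen after the data were seen; the others were planned. No result changed sign while called. The cause was not tested, except that a stricter filter tests fewer peaks and left-out libraries mean fewer samples.

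The 5 calls of Stat6_KO against WT became 3 with the stricter filter, 38 (21 higher, 17 lower) in a fit of the 2 groups alone, 108 (61 higher, 47 lower) with array weights, 67 (35 higher, 32 lower) without WT 1 and Il21e_KO 1, and 3 to 61 with each library left out in turn. The 0 calls of Il21e_KO against WT became 1 (the Pkdcc peak) without a filter and 4 with array weights, and 0 to 2 with each library left out. The 5 calls of Stat6_KO against Il21e_KO became 13 (1 higher, 12 lower) with cyclic loess, 16 (3 higher, 13 lower) without a filter, 3 with the stricter filter, 8 with a pseudocount of 5, 10 (2 higher, 8 lower) with edgeR, 36 (7 higher, 29 lower) with array weights, and 4 to 17 with each library left out. With the replicate number as a block (replicate block), the counts were 4, 0 and 5, of which 4 and 4 were among the calls as reported.

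The 1 Stat6 locus peak passing over the locus alone against WT became 2 with DESeq2 size factors, cyclic loess, no filter, DESeq2, limma-voom, a fit of the 2 groups and the replicate block, 0 with the stricter filter, and 0 to 2 with each library left out. The 2 against Il21e_KO became 0 with the stricter filter, 1 in a fit of the 2 groups, and 1 to 2 with each library left out. The 0 Il21 locus peaks in Il21e_KO against WT stayed at 0 in every setting run. From 0 gene lists, 1 passed in Stat6_KO against WT (early T cell receptor response, lower) with 1 peak per gene without Il21e_KO 1, and 0 when that correlation was estimated (adjusted p = 0.842). In Stat6_KO against Il21e_KO, 2 passed with 1 peak per gene and 1 (early T cell receptor response, lower) with only the peaks the authors assigned, where no estimated correlation was run.

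The covariance less that computed from the shared WT libraries (0.0322), -0.00784 in the fit as reported, was -0.0189 with the replicate block and -0.0174 to 0.0112 with each library left out, positive only without Il21e_KO 1. Peaks near Stat6, 0 among the calls, were counted at an unadjusted p under 0.01 within 10, 5 and 20 Mb. Of 437, 214 and 577 tested peaks they numbered 8, 7 and 8 in Stat6_KO against WT, and 11, 8 and 12 in Stat6_KO against Il21e_KO. Near Il21 in Il21e_KO against WT they numbered 1, 1 and 2. Calls at a TSS, 0 in both Stat6_KO comparisons, were 38 of 265 and 97 of 365 at that p.

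Of 246 alternative values for the 10 passing named values, 218 kept direction and call and 28 kept the direction alone. For the 50 named values that did not pass, 1119 of 1225 stayed so with the same direction, 44 passed and 62 changed sign without passing. For the 7 locus peaks, 94 of 115 kept direction and call, 6 lost the call, 10 gained it and 5 changed sign without passing. Depth limits what could be seen: 67440 of 115727 peaks were too shallow to test, and simulated 1.5-fold changes were recovered in at most 7.46% of peaks.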

Other observations

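The genes below were chosen after their values were seen, from the fit of 8 libraries without Il21e_KO 1, where 61 peaks passed in Stat6_KO against WT. Promoter peaks were lower at Vamp4, a vesicle fusion protein gene (-0.74 ± 0.14, SE), Cisd2 of the mitochondrial and ER membranes (-0.74 ± 0.16), Taf4b of the general transcription machinery (-0.70), Ibtk, an inhibitor of the B cell kinase BTK (-0.60), and Paxbp1 (-0.64). Promoter peaks were higher at Sox30 (1.40) and Lrig3 (1.44 ± 0.33), the first in the chromosome 11 region and the second within 10 Mb of Stat6. Intron 4 of the phosphatase gene Ppm1h (-1.04), also within 10 Mb of Stat6, was lower, as was an exon peak of the histone deacetylase gene Hdac9 in the chromosome 12 region (-2.22). Near Csrnp1, an early response transcription factor gene, the TTS peak was higher (0.72 ± 0.16). In all, 4 of the 61 peaks lay within 10 Mb of Stat6.

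The regional scan without Il21e_KO 1 gave 5 bins in Stat6_KO against WT, 1 in Il21e_KO against WT and 4 in Stat6_KO against Il21e_KO, against 4, 0 and 3 with all 9 libraries. Of the 17 peaks that passed in Stat6_KO against Il21e_KO by this fit, 11 lay in the bins passing with all libraries, and 0 were at a TSS. The bins were picked for low p in largely the same libraries, which favours this overlap.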
